A study of Gallus gallus with 10 samples.

How the data were processed

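The series holds 10 samples in 4 groups: small RNA from sorted neural crest and neural plate cells, with 3 libraries each, and poly(A) RNA from neural plate reporter-positive and reporter-negative cells, with 2 libraries each. Per the labels' protocols, RNA was taken from 10000 cells per small RNA library and 5000 per poly(A) library, small RNA was read at 37 bp and poly(A) RNA at 150 bp, in pairs, and the poly(A) kit keeps strand. Groups and replicate numbers were taken from the sample titles.

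The small RNA counts were deposited as whole-number read counts per mature miRNA name, per the file headers and values, and the submitters' processing notes name CASAVA 1.8, Bowtie and the galGal5 build. The poly(A) counts were deposited as whole-number read counts per Ensembl gene, and the submitters' processing notes name CASAVA 1.8, cutadapt, HISAT2 and featureCounts on galGal5. The log2 fold changes and their standard errors were made by the authors with DESeq2, per the file headers. The p-values and adjusted p-values of those tables were also made by the authors with DESeq2, per the file headers. The score columns are the mean of normalized counts and the Wald statistic of the authors' DESeq2 comparison, per the file headers. The strand setting, the annotation version and the tool that counted small RNA are not given in the sources used here. The direction of the authors' gene table is not stated in its header and was read from SOX2 and TFAP2A. Of the authors' miRNA table, 99.2% of the 719 names with a count had a sign opposite to neural crest over neural plate in the counts, so its positive values are higher in neural plate.

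Among the poly(A) counts, 2 columns of per-sample values have names that point to sorted neural crest but match no sample of the series, and they were used in no step. Counts of the reporter-negative libraries were not analysed here. The planned comparison of reporter-positive with reporter-negative cells, its gene lists, the part of the naming rule on its largest changes and its alternatives were therefore not run. The authors' deposited gene table was described by the fixed gene lists instead, which was decided after the files were seen.

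Identical repeated lines of the same name were dropped, 109 of 1327 in the miRNA table and 1423 of 11458 in the poly(A) table. Total counts were 402824, 997284 and 1772040 in neural plate and 274327, 275898 and 740728 in neural crest small RNA, and 12661841 and 10254529 in the reporter-positive poly(A) libraries. A count of 0 (up to 3 counts) allows 1.69 to 10.9 CPM in the small RNA and 0.237 and 0.293 CPM in the poly(A) libraries. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. The miRNAs miR-26a-2-5p and miR-26a-5p have identical counts. Library pairs were compared by chi-square per degree of freedom, which was 19.1 to 952 among small RNA pairs and 48.0 for the poly(A) pair, so no library was taken for a copy of another.

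MiRNA counts of neural crest and neural plate were compared in R 4.3.3 with edgeR 4.0.16 (filterByExpr with a count minimum of 10 and a total of 15, TMM factors, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjustment, no block). TMM factors were 0.700, 0.966 and 0.843 in neural plate and 1.18, 1.24 and 1.20 in neural crest. CPM are scaled by these factors in the comparison, and shares are of the total count. The common biological coefficient of variation was 0.523. Families with at least 3 tested members were tested with limma 3.58.1 (camera on voom values, preset correlation 0.01), with an estimated correlation and fry beside it. Families with fewer than 3 tested members were not tested. Gene lists were tested with limma's cameraPR on the Wald statistic of the authors' table, and counts adjusted over the list alone re-adjust the authors' p-values within a list. The median of each list was also placed among 10000 random lists of the same size matched on the mean normalized count. Shares of counts were compared by two-sided exact permutation tests. CPM in the reporter-positive libraries are over the total count, and their correlation used log2(CPM + 1) of genes with a mean of at least 1 CPM.

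The design, the lists, the rule for names and the alternatives in the miRNA comparison were chosen before the data were examined. The named miRNAs are up to 12 per direction with the largest change among those with an adjusted p under 0.05, a mean of at least 50 CPM and no overlap of the groups, the 8 of highest mean CPM, and all arms of miR-20a, miR-200a, miR-217, miR-302a to miR-302d, miR-9, miR-10a, miR-10b and miR-205. The named genes are up to 4 members per direction with the smallest adjusted p in each list, and SOX2, TFAP2A, SNAI2, FOXD3, PAX7, FGF3, FGF4, FGF8, FGF19, FGFR1 to FGFR4, SPRY1, SPRY2, DUSP6, ETV4, ETV5, DICER1, DROSHA, DGCR8, AGO2, LIN28A and LIN28B. Besides the genes said not to be analysed here, 1 gene that the rule names is not reported here. Gene neighbours were taken from a RefSeq table of assembly GRCg7b, which holds 99.5% of the genes of the authors' table by Entrez ID. That assembly differs from galGal5, so no coordinates are given. Overlaps were found with GenomicRanges 1.54.1.

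The test was run first on simulated counts of 719 names, 200 of them changed. It recovered 16 of 35 tested names with a 4-fold change (45.7%) and 44 of 44 with a 16-fold change. It also called 5 of 144 unchanged names (3.47%), which is a share of the unchanged names and not of the calls. The simulated names varied independently of each other. In the simulated families the 1 changed family was called and 0 others. Alternatives for miRNAs were RLE factors, library totals alone, no filter, a filter of 10 CPM in every library of a group, DESeq2 1.42.0, limma-voom, a replicate block, each library left out, an adjusted p of 0.1 and a fold of at least 2. Alternatives for the authors' table, and the fit without the libraries at both ends of the first component, were added after seeing the data.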

Results

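Cells were sorted from dissected heads of chicken embryos at Hamburger-Hamilton stage 8 (HH8), when the neural crest is forming at the edge of the neural plate. Embryos had been transfected at HH4 with fluorescent reporters driven by tissue-specific enhancers. Neural crest cells were taken by a Tfap2a enhancer driving GFP. Neural plate cells were taken by the Sox2 N2 enhancer driving eGFP, used together with a reporter for non-neural ectoderm and neural crest. Small RNA was sequenced from 3 neural crest and 3 neural plate libraries of 10000 cells each. Poly(A) RNA was sequenced from neural plate reporter-positive and reporter-negative cells, with 2 libraries of 5000 cells in each group, and the counts of the positive libraries are described here. The title of the series places these data in a study of how FGF (fibroblast growth factor) signalling is tuned after transcription during neural crest induction.

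The neural plate small RNA libraries held 402824, 997284 and 1772040 counts over miRNA names in replicates 1, 2 and 3. The neural crest libraries held 274327, 275898 and 740728. Of 1218 mature miRNA names, 719 had at least 1 count, and 28.2% of these passed the filter for testing. In a principal component analysis the first component held 65.6% of the variance, with neural plate replicate 1 at its low end (-20.5) and neural crest replicate 3 at its high end (13.2). The other libraries lay at -3.31 and -0.838 (neural plate replicates 2 and 3) and at 6.54 and 4.90 (neural crest replicates 1 and 2). Every neural plate library thus lay below every neural crest library on this component. The labels do not say whether the libraries came from separate pools of embryos, so the p-values measure only the spread between these libraries, which may be technical.

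The miR-302 cluster, which marks pluripotent and early embryonic cells, made up most of the miRNA counts in both tissues. It took 62.9% ± 3.98 (SD, n = 3) of the counts in neural crest and 67.0% ± 3.33 (SD, n = 3) in neural plate. A two-sided exact permutation test gave p = 0.3 for that difference, where 3 against 3 libraries cannot go below 0.1. The miR-17-92 cluster and its paralogous cluster, known as promoters of proliferation, together took 16.9% ± 2.68 and 14.3% ± 2.61 (SD, n = 3 each, exact permutation p = 0.3). The let-7 family, which rises as embryonic cells mature, took 0.308% ± 0.110 and 0.247% ± 0.0332 (SD, n = 3 each, exact permutation p = 0.4). By mean CPM over all 6 libraries the 8 most abundant names were miR-302b-3p, miR-302b-5p, miR-302d, miR-92-3p, miR-363-3p, miR-302c-3p, miR-2954 and miR-130b-3p, an order that not every library kept. In neural plate replicate 1, for example, miR-302b-5p took 38.7% of the counts and miR-302b-3p 21.8%. The name miR-302b-3p took 29.2% ± 0.645 of the counts in neural crest and 30.7% ± 8.12 in neural plate (SD, n = 3 each, exact permutation p = 0.7). The 10 most abundant names of each library together took 81.0% ± 1.38 in neural crest and 88.2% ± 1.82 in neural plate, without overlap of the groups (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Mature miR-302 names differ from each other by few bases, as do members of the miR-17 family, so the split of reads among them is uncertain.

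The comparison of neural crest with neural plate asks which miRNAs distinguish these neighbouring tissues. Neural crest libraries held more of miR-203a, a miRNA of epidermal differentiation, at 1010.5 ± 182.6 TMM-scaled counts per 1e+06 (CPM) against 143.7 ± 57.4 in neural plate (SD, n = 3 each), a 6.97-fold difference. They held more of miR-200b-3p, of the epithelial miR-200 family, at 10843 ± 2699.8 CPM against 2354 ± 1065 (SD, n = 3 each; 4.60-fold). The muscle miRNA miR-1a-3p (4.93-fold), miR-101-3p (4.81-fold) and miR-217-5p (4.76-fold) were higher in neural crest as well, the first at 301.9, 232 and 691 CPM and the second at 992, 863 and 2413 CPM in neural crest replicates 1, 2 and 3. Neural plate libraries held more of miR-2954, known in birds as a Z-linked, male-biased miRNA, at 52643 ± 14858 CPM against 10247 ± 4981 in neural crest (SD, n = 3 each; 5.14-fold), and more of miR-18b-3p, at 1060.2 ± 164.2 against 220.5 ± 14.6 CPM (SD, n = 3 each; 4.80-fold). The sample settings used here hold no sex of the embryos, so for miR-2954 tissue and sex cannot be told apart.

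In edgeR's quasi-likelihood test, 15 miRNAs passed a Benjamini-Hochberg adjusted p of 0.05, with 7 higher in neural crest and 8 higher in neural plate. By edgeR the adjusted p was 0.0385 for miR-203a, miR-200b-3p, miR-217-5p, miR-2954 and miR-18b-3p, and 0.0464 for miR-1a-3p and miR-101-3p. The log2 fold change, neural crest over neural plate, was 2.80 with a standard error of 0.558 for miR-203a and 2.20 with a standard error of 0.530 for miR-200b-3p. Among the others, miR-425-5p was 9.02-fold higher in neural plate, where the libraries read 15429, 2695 and 2443 CPM. miR-12277-5p (16.6-fold), miR-6599-3p (7.97-fold) and miR-1774 (7.60-fold) were higher in neural plate too, and miR-12277-5p had only 2, 3 and 8 counts in the neural crest libraries. Neural plate replicate 1 set much of these folds: without it the log2 fold change went from -3.17 to -1.63 for miR-425-5p, from -4.05 to -1.78 for miR-12277-5p, from -2.995 to -2.11 for miR-6599-3p and from -2.93 to -1.90 for miR-1774, and the first 2 were no longer called by edgeR (adjusted p = 0.0523 each). Without neural crest replicate 3 the log2 fold change went from 2.30 to 1.82 for miR-1a-3p and from 2.27 to 1.801 for miR-101-3p, and without neural plate replicate 2 from 2.25 to 2.92 for miR-217-5p. The remaining called miRNAs averaged below 50 CPM and are named after their values were seen. Of these miR-499-5p (9.47-fold), which lies in a myosin gene, and miR-1799 (4.84-fold) were higher in neural crest, and miR-1553-5p (9.06-fold) and miR-12266-5p (8.64-fold) in neural plate. Single libraries weighed on these too: miR-1553-5p read 92.4, 30.1 and 20.8 CPM in neural plate, with 0, 2 and 6 counts in neural crest, and miR-499-5p read 33.9, 20.5 and 81.4 CPM in neural crest. The groups did not overlap in TMM-scaled CPM for 82 of the tested miRNAs (40.4%), where chance gives 10% for a single miRNA. All miRNAs share the same 6 libraries, so their overlaps are not independent and the 2 percentages do not make a test. The TMM factors, lower in every neural plate library than in any neural crest library, enter these CPM too.

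Leaving out any 1 neural crest library left 0 calls by edgeR, with 49, 62 and 39 miRNAs at an unadjusted p under 0.05 without replicates 1, 2 and 3, while 23 and 7 were called without neural plate replicates 1 and 2 (none of the 7 higher in neural crest), and 60 without both libraries at the ends of the first component, a choice made after seeing the data. DESeq2 called 35 miRNAs, a fit without the filter 26, and scaling by the library total alone, which raised the log2 fold changes by a median of 0.51, called 23, with 18 higher in neural crest and 5 in neural plate.

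**Figure D1:**
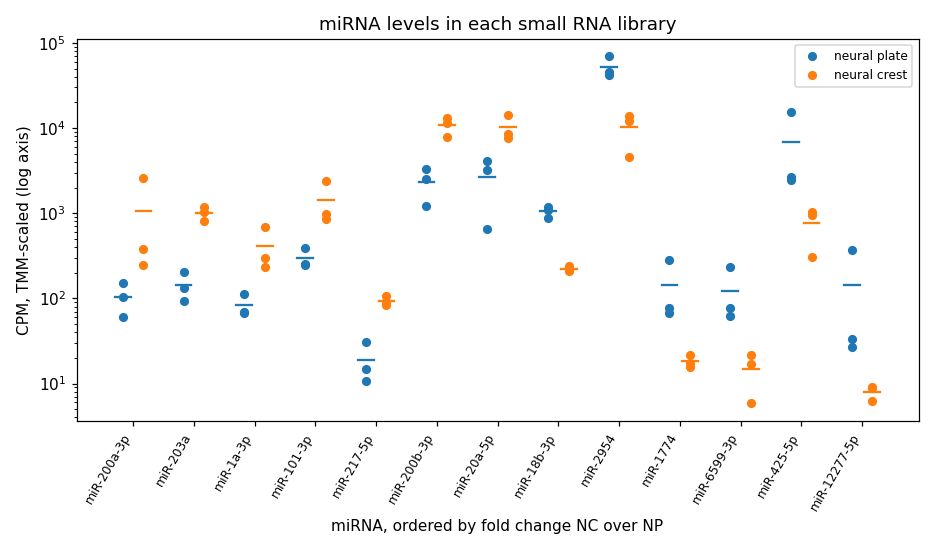
TMM-scaled CPM (log axis) of 13 miRNAs in the 3 neural plate and 3 neural crest small RNA libraries, with 1 point per library and a bar at each group mean. Neural crest miR-203a sits at 1010.5 CPM on average against 143.7 in neural plate, while miR-2954 sits at 10247 against 52643, and miR-200a-3p and miR-20a-5p did not pass the test.

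A few miRNAs were fixed in advance. Of these miR-217-5p passed the test, at 93.8 ± 12.3 CPM in neural crest and 18.9 ± 10.9 in neural plate (SD, n = 3 each). It had only 3, 30 and 22 counts in the neural plate libraries. Its cluster mate miR-216b, named after its value was seen, lay the other way without passing (log2 fold change -0.97, edgeR adjusted p = 0.218). For miR-200a-3p the means were 1073 ± 1321 CPM in neural crest and 105 ± 45.2 in neural plate (SD, n = 3 each; edgeR adjusted p = 0.0518). Its neural crest libraries read 379, 244 and 2597 CPM, so replicate 3 set the mean, and the log2 fold change of 3.34 was 1.67 without that library. For miR-20a-5p, of the miR-17-92 cluster, the means were 10156 ± 3511 and 2657 ± 1788 CPM (SD, n = 3 each; edgeR adjusted p = 0.0877). Both passed with DESeq2, and by edgeR both passed without neural plate replicate 1 (adjusted p = 0.0422 and 0.0260). Over all alternatives the adjusted p ran from 1.76e-04 to 0.153 for miR-200a-3p and from 8.93e-06 to 0.252 for miR-20a-5p, with edgeR, limma or DESeq2. In the authors' deposited table of their DESeq2 comparison these adjusted p-values were 0.00114 and 0.0281, and 0.00475 for miR-217-5p. That comparison was made from the same libraries, so a pass here is not independent support for these miRNAs. No reason for fixing them was recorded. The authors' deposited table lists 32 miRNAs under an adjusted p of 0.05, of which 17 were higher in neural crest and 15 in neural plate, and these include the 15 called here.

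Other miRNAs fixed in advance did not pass the edgeR test. The neural miRNA miR-9-5p averaged 491 ± 320.2 CPM in neural crest and 215.4 ± 67.7 in neural plate (SD, n = 3 each, edgeR adjusted p = 0.204). Its neural crest libraries read 373, 246 and 853 CPM, so replicate 3 set much of that mean. The other arm miR-9-3p had an edgeR adjusted p of 0.405. The edgeR adjusted p was 0.349 for miR-10a-5p and 0.477 for miR-10b-5p, both from Hox clusters, 0.752 for the epithelial miR-205a and 0.281 for miR-200a-5p. Of the miR-302 arms none passed by edgeR, with adjusted p of 0.532 for miR-302a, 0.234 for miR-302b-3p, 0.164 for miR-302b-5p, 0.502 for miR-302c-3p, 0.274 for miR-302c-5p and 0.809 for miR-302d.

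Of 20 miRNA families fixed in advance, 14 had at least 3 tested members. The miR-200 family, which keeps cells epithelial by restraining ZEB factors, was higher in neural crest: its 4 measured arms (miR-200a-3p, miR-200a-5p, miR-200b-3p and miR-429-3p) had positive fold changes, with a median of 2.24 on the log2 scale. Of these 1 passed over all miRNAs, and 3 passed adjusted over the list alone. The family had an adjusted p of 0.0377 by limma's camera with a preset correlation of 0.01, and an adjusted p of 0.489 with an estimated correlation. It also missed the threshold by fry (0.0524), with library totals alone (0.0894), without neural plate replicate 2 (0.0543) and without neural crest replicate 3 (0.0542). Of 16 non-neural ectoderm and placode genes in the authors' deposited table, 8 were higher in neural crest too, such as DLX3 (10.9-fold) and GATA3 (7.42-fold). The epithelial cadherin CDH1 was 24.5-fold higher in neural plate there, and the epithelial gene EPCAM did not pass (DESeq2 adjusted p = 0.645). As a list the 16 ectoderm and placode genes, which include CDH1 and EPCAM, did not pass (adjusted p = 0.146 by limma's cameraPR). Their median lay at percentile 0.18 among random lists of like expression, at the neural crest end, which takes no account of correlation between genes. ZEB2, the ZEB factor in the fixed lists, was 2.20-fold higher in neural crest (DESeq2 adjusted p = 0.00240), the same side as the miR-200 family.

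The other families did not pass camera. In the muscle and heart family miR-1a-3p and miR-499-5p were called, 2 of 4 members, with 3 adjusted over the list alone, while miR-206 had a negative fold change of -0.65 on the log2 scale (0.114 by camera, 0.489 with an estimated correlation). By limma it passed only with fry (0.0369), which does not compare it with other miRNAs, and without neural crest replicate 1 (0.0307). In the epithelial and ectodermal family of 5, miR-203a was called, with 1 up and 1 down adjusted over the list alone (0.668 by camera, 0.0162 by fry). In the miR-17 family and its cluster mates 8 arms had positive and 8 negative fold changes, and miR-18b-3p was called, as it was adjusted over the list alone (0.910). The split went by arm only in part, as seen only after the test. Positive were the 5p arms of miR-17, miR-18a, miR-18b, miR-20a, miR-20b and miR-106, and miR-19a-3p and miR-19b-3p (log2 0.83 to 1.93, none called). For each of these neural plate replicate 1 read lowest. Negative were the arms of miR-92 and miR-363 and the 3p arms of miR-18a, miR-18b, miR-20b and miR-106. No member was called, over all miRNAs or adjusted over the list alone, among 13 neural miRNAs (0.604), the 8 of let-7 (0.668) and the 8 of the miR-302 cluster (0.910), whose median of -0.39 and mean of 0.03 differed in sign and whose median was 0.13 with library totals alone. The same held for the mesenchymal miR-199-3p, miR-143-3p and miR-145-5p (0.567), miR-30 (0.753), miR-23, miR-24 and miR-27 (0.753, median -0.09 but mean 0.23), the endodermal miRNAs (0.768), miR-130 and miR-301 (0.910), miR-99, miR-100 and miR-125 (0.910) and miR-181 (0.910), each an adjusted p by limma's camera.

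The neural plate reporter-positive poly(A) libraries held 12661841 and 10254529 counts over 10035 Ensembl genes. Their log2 CPM correlated at r = 0.975 across 8261 genes, which are not independent replicates. SOX2 (ENSGALG00000043460), the neural plate factor whose enhancer drove the reporter, was read at 62.3 ± 2.16 CPM (SD, n = 2). TFAP2A (ENSGALG00000012775), a factor of the neural plate border and ectoderm, was read at 31.6 ± 4.64 CPM, and the border and crest factor PAX7 (ENSGALG00000043204) at 7.96 ± 2.54 CPM (SD, n = 2 each). Among the FGF receptors FGFR1 was read at 767 ± 16.5 CPM, FGFR3 at 182.97 ± 44.6 and FGFR2 at 153.1 ± 10.3 CPM (SD, n = 2 each). LIN28A, which blocks let-7 maturation, was read at 828 ± 38.2 CPM, and DICER1, which cuts miRNA precursors, at 171 ± 66.0 CPM (SD, n = 2 each). No group comparison was made from these counts.

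Gene expression in neural crest and neural plate was compared by the authors with DESeq2. Counts of the neural crest side were not used here, so those fold changes were not recomputed from libraries. The authors' deposited table lists 1457 of 8087 genes under an adjusted p of 0.05, 978 higher in neural crest and 479 higher in neural plate. The sign of the authors' deposited table was read from SOX2, 14.8-fold higher in neural plate, and TFAP2A, 13.9-fold higher in neural crest, so the directions of these genes are not results. Among the named genes, TFAP2B, PAX7 and CDH1 changed by over 4 on the log2 scale. Reporter-positive counts were 71 and 37 for TFAP2B and 78 and 100 for PAX7, against mean normalized counts of 1700 and 1196. For CDH1 they were 21028 and 12740 against 9758. These lie on the side that the sign gives, though the counts are not normalized and the libraries in that mean are not stated. Log2 fold changes from the authors' deposited table are given with its standard error (SE), and a single value in parentheses after a list is that list's adjusted p by limma's cameraPR. Several of the named genes overlap another gene, and their reads are uncertain: SNAI1, TFAP2C, BMPR2, HES5, DLL1, FGF13, CCNE2, JUN, HAPLN1 and DROSHA. LHX2, CDH1, CDON, AGO3, PCNA, HSPA5, LAMA5 and TNNT2 lie within 1 kb of another gene, and without all such genes 691 of 3343 remained past the threshold in the authors' deposited table.

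Neural crest and border genes stood apart in the authors' deposited table. Of 15 measured neural crest specifiers in the authors' deposited table, 11 were higher in neural crest, 1 was higher in neural plate and 3 did not pass, with 13 and 1 adjusted over the list alone. The authors' deposited table gave log2 fold changes towards neural crest of 5.79 for TFAP2B (SE 0.375), 3.68 for the ligand BMP5 (SE 0.393) and 3.67 for the early crest factor SOX9 (SE 0.404). SNAI1, a repressor linked to epithelial-mesenchymal transition, was the gene higher in neural plate, at 1.76 (SE 0.597) in the authors' deposited table. Of 12 neural plate border genes in the authors' deposited table, some of them shared with the specifiers, 10 were higher in neural crest, also 10 adjusted over the list alone. PAX7 was 22.2-fold higher in neural crest in the authors' deposited table, with log2 fold changes of 3.06 for MSX1 (SE 0.323) and 3.47 for TFAP2C (SE 0.400). On the statistic of the authors' deposited table, limma's cameraPR gave an adjusted p of 2.26e-19 for the specifiers and 3.19e-18 for the border genes over 23 lists. Without TFAP2A and SOX2, which set its sign, the authors' deposited table had 10 of 14 specifiers and 9 of 11 border genes higher in neural crest, and 12 and 9 adjusted over the list alone, and both lists still passed (2.53e-15 and 7.23e-14).

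WNT, BMP and FGF feedback genes were higher in neural crest as groups in the authors' deposited table, while the other signalling lists did not pass. In the WNT pathway 12 of 20 measured members of the authors' deposited table were higher in neural crest, with 14 and 2 towards neural plate adjusted over the list alone. They included the ligand WNT6 (3.86, SE 0.543), the WNT inhibitor NKD1 (3.13, SE 0.374), the receptor FZD10 (2.95, SE 0.454) and the target SP8 (2.72, SE 0.364) in the authors' deposited table. In the BMP pathway 9 of 15 members of the authors' deposited table were higher in neural crest, 10 adjusted over the list alone, among them the antagonist FST (2.03, SE 0.325), the inhibitory SMAD7 (2.02, SE 0.477) and the receptor BMPR2 (1.42, SE 0.368). Of 14 FGF feedback and target genes in the authors' deposited table, 7 were higher in neural crest, 8 adjusted over the list alone, and 0 in neural plate. DUSP5, an ERK phosphatase, had 3.54 (SE 0.523), the receptor signalling inhibitor SPRY1 3.24 (SE 0.608), FOS 1.56 (SE 0.460) and SPRED2 1.36 (SE 0.346) in the authors' deposited table. SPRY2, DUSP6 and ETV5 did not pass in the authors' deposited table, with adjusted p of 0.294, 0.0618 and 0.721. On the authors' deposited table the adjusted p by limma's cameraPR was 7.51e-07 for WNT, 2.26e-05 for BMP and 0.00451 for FGF feedback.

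FGF ligands and receptors differed both ways in the authors' deposited table and did not pass as a list (16 measured, 0.694 by limma's cameraPR). FGFR2 was 2.95-fold and FGF13 3.14-fold higher in neural plate in the authors' deposited table. FGFR3 was 2.70-fold, the ligand FGF8 2.44-fold and FGF14 4.98-fold higher in neural crest in the authors' deposited table, and the same counts of 2 and 3 held adjusted over the list alone. FGFR1, FGFR4, FGF3 and FGF19 did not pass in the authors' deposited table, with adjusted p of 0.995, 0.897, 0.805 and 0.706. Among 11 miRNA biogenesis and silencing genes (0.694), DICER1 was 2.18-fold and the Argonaute gene AGO3 1.86-fold higher in neural plate in the authors' deposited table. LIN28B was 3.02-fold and LIN28A 2.01-fold higher in neural crest in the authors' deposited table, and adjusted over the list alone 3 genes passed towards neural plate and 2 towards neural crest. DROSHA, which starts miRNA processing in the nucleus, did not pass in the authors' deposited table (adjusted p = 0.749). SNAI2, FOXD3, FGF4, ETV4, DGCR8 and AGO2 were not analysed here.

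Forebrain and midbrain patterning genes were higher in neural crest for 10 of 12 members of the authors' deposited table, also 10 adjusted over the list alone, with a limma cameraPR adjusted p of 5.84e-07. Examples from the authors' deposited table are LHX2 (2.97, SE 0.429) and PAX6 (2.35, SE 0.319) of the eye field and forebrain, and EN1 (2.01, SE 0.463) and PAX2 (1.87, SE 0.315) of the midbrain. Of 13 pan-neural genes in the authors' deposited table, 6 were higher in neural crest and SOX2, which set the sign, in neural plate, with 6 and 3 adjusted over the list alone (0.191). Without SOX2 and TFAP2A, a choice made after seeing the data, the pan-neural list of the authors' deposited table passed towards neural crest by limma's cameraPR (0.0127, where its other alternatives ran from 0.200 to 0.782), with 6 of 12 genes higher in neural crest and 0 in neural plate, and 6 and 2 adjusted over the list alone. SOX21 (1.70, SE 0.305) and ZIC2 (1.55, SE 0.281), which is also known from the dorsal neural folds, were among the 6 in the authors' deposited table. Of 14 Notch pathway genes in the authors' deposited table, 5 were higher in neural crest, with the targets HES5 (2.25, SE 0.364) and HES1 (1.07, SE 0.338) and the ligands DLL1 (1.51, SE 0.345) and JAG2 (1.25, SE 0.417), and NOTCH2 was higher in neural plate. The Notch list did not pass on the authors' deposited table (0.115, with 1 and 6 genes adjusted over the list alone).

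Lists of markers of other cell types that the gates could hold did not pass by limma's cameraPR on the authors' deposited table. Some of their members passed there on their own. Of 16 non-neural ectoderm and placode genes in the authors' deposited table, 8 were higher in neural crest and 1 in neural plate, the same counts adjusted over the list alone. DLX3 (3.45, SE 0.645), DLX6 (3.13, SE 0.468), GATA3 (2.89, SE 0.688) and DLX5 (2.14, SE 0.372) led them, while the epithelial cadherin CDH1 was 24.5-fold higher in neural plate in the authors' deposited table. That list did not pass on the authors' deposited table (0.146). Over all genes 978 of 8087 were higher in neural crest, against 8 of 16 in the list. Its median lay at percentile 0.18 among random lists of like expression, at the neural crest end. Its adjusted p ran from 0.00971 without genes within 1 kb of another to 0.296 with a preset correlation of 0.05. Leaving out genes within 1 kb drops CDH1, the 1 member that passed towards neural plate, along with other members. The list without CDH1 alone was not tested. Of 15 cadherin and junction genes in the authors' deposited table, CDH1 and, towards neural crest, CDH6 (3.97, SE 0.380) passed, as they did adjusted over the list alone (0.111). The blood and endothelial factors FLI1 and TAL1 were 12.7-fold and 3.54-fold higher in neural plate in the authors' deposited table, 2 of 12 measured and 1 adjusted over the list alone (0.143). The heart muscle gene TNNT2 was 3.83-fold higher in neural plate and BMP4 2.46-fold higher in neural crest in the authors' deposited table, 2 of 18 heart and lateral mesoderm genes and the same adjusted over the list alone (0.335).

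Of 20 cell cycle genes in the authors' deposited table, PCNA (2.24-fold), CCNE2 (2.16-fold), MCM2 (1.76-fold) and MKI67 (1.75-fold) were higher in neural plate and CCND2 (2.04-fold) in neural crest, with 5 and 1 adjusted over the list alone. The cell cycle list had 0.0664 on the authors' deposited table, and from 0.0267 on ranks to 0.228 with a preset correlation of 0.05. Of 10 stress and immediate early genes in the authors' deposited table, GADD45A and HSPA5 were higher in neural plate and JUND, FOS, IER5 and JUN in neural crest, with 2 and 5 adjusted over the list alone (0.694). Of 10 Hedgehog pathway genes, GLI3, OLIG2, BOC and CDON were higher in neural crest in the authors' deposited table, also 4 adjusted over the list alone. The median of 0.22 in that list, neural plate over neural crest, differed in sign from its mean of -0.42 in the authors' deposited table (0.191). Higher in neural crest in the authors' deposited table were 1 of 6 notochord genes (NOTO), 1 of 6 hindbrain genes (IRX2) and 2 of 14 matrix genes (HAPLN1 and LAMA5), the same counts adjusted over the list alone (0.995, 0.995 and 0.963). The notochord median of -0.04 and mean of 0.03 in the authors' deposited table differed in sign, and the hindbrain median of 0.11 and mean of 0.02 lay on the other side from its test. No member passed, adjusted over the list alone or over all genes, in the paraxial mesoderm (0.569), endoderm (0.766) and retinoic acid (0.707) lists of the authors' deposited table. Of the 23 lists 6 passed on the authors' deposited table, all towards neural crest, and also with a preset correlation of 0.05, while an estimated correlation needs libraries. Medians of some lists that did not pass still lay far out among 10000 random lists of like expression drawn from the authors' deposited table, which takes no account of correlation between genes. Counted towards neural plate, the percentile was 100 for heart and lateral mesoderm, 99.4 for blood and endothelium and 97.9 for paraxial mesoderm in the authors' deposited table, and at the neural crest end 2.39 for stress genes, 0.18 for non-neural ectoderm, 0.09 for pan-neural and 0 for Notch genes.

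**Figure D2:**
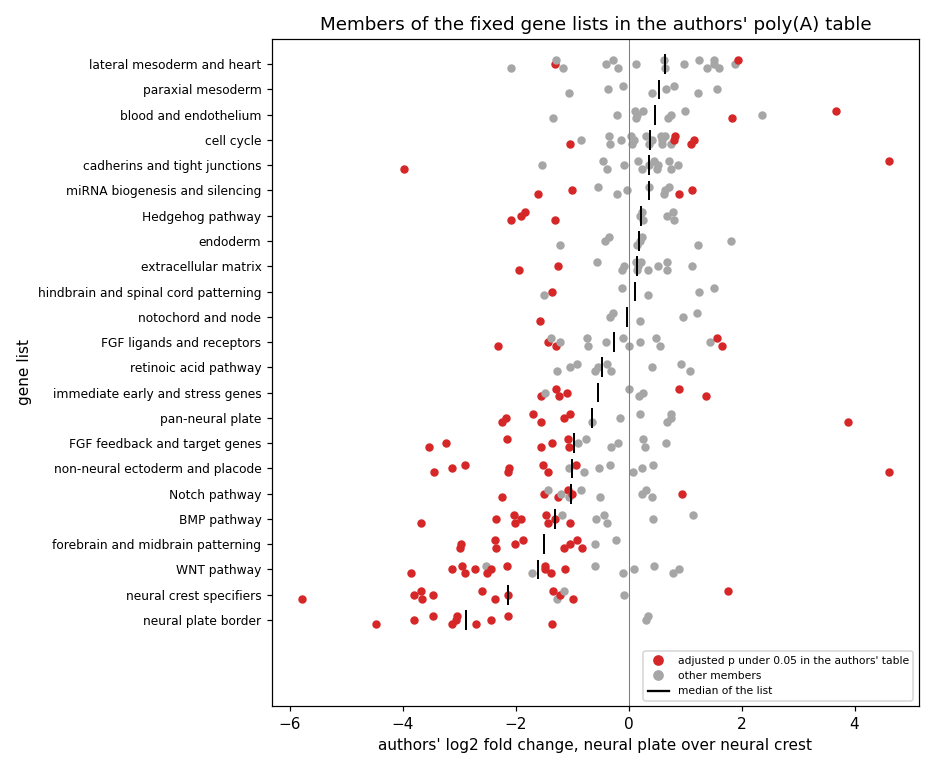
Log2 fold change, neural plate over neural crest, in the authors' deposited table (horizontal axis) for members of the 23 fixed gene lists (vertical axis, ordered by median). Each point is a gene, red where the adjusted p in that table was under 0.05 and grey otherwise, and the black bar is the list median, which was -2.88 for neural plate border genes and 0.64 for heart and lateral mesoderm genes.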

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

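The alternatives on the authors' deposited tables and the fit without neural plate replicate 1 and neural crest replicate 3 were chosen only after the results were seen. The 15 called miRNAs became 23 with library totals alone, 26 without the filter, 35 with DESeq2, 45 at an adjusted p under 0.1 and 60 without neural plate replicate 1 and neural crest replicate 3. With RLE factors, the stricter filter, limma-voom and a minimum fold it moved less than 1.5 times. With each library left out it ran from 0 (any neural crest library) to 23 (neural plate replicate 1). With a replicate block 26 were called. The labels do not say whether shared numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.0688, -0.138 and 0.0844, and 2 of 6 libraries correlated best with their own number. With so few libraries per group these values cannot exclude a pairing. RLE factors shifted the log2 fold changes by a median of 0.11, with 9 changes of sign, and library totals alone gave 36. Of 20 miRNA families 1 was called, 0 with an estimated correlation, 2 with fry, 0 with library totals alone, and 0 to 2 with each library left out. Library totals alone also turned the median of let-7 from -0.28 to 0.27 and of miR-130 and miR-301 from -0.30 to 0.17, and, as RLE factors did, changed the sign for miR-99, miR-100 and miR-125 (-0.07 to 0.49) and miR-23, miR-24 and miR-27 (-0.09 to 0.41). The 11 called miRNAs named by the rule kept their sign in all 154 alternative values and lost the call in 50; the 17 others kept it in 226 of 238 and gained a call in 16. Without genes within 1 kb of another, 691 of 3343 genes passed in the authors' deposited table, against 1457 of 8087; fewer genes were counted. Its 6 called gene lists passed under each of 5 alternatives, and without SOX2 and TFAP2A there were 7. The cause of the other moves was not tested. In simulated counts with the depths and spread of these libraries, changes of 4-fold were partly undetected. The alternatives meant for reporter-positive against reporter-negative cells were not run.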

Other observations

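The tests on splits of the libraries, on the libraries at the ends of the first component, on differences within groups over miRNAs, on list members among extreme genes and on batch were chosen only after the result was seen, and so was each miRNA and gene named in this part.

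Several miRNAs in the authors' deposited table's calls just missed the edgeR threshold. miR-148b-3p averaged 8773 ± 446 CPM in neural crest and 3584 ± 822 in neural plate (SD, n = 3 each; edgeR adjusted p = 0.0877). miR-21-5p averaged 14883 ± 4837 and 5139 ± 2868 CPM (SD, n = 3 each; edgeR adjusted p = 0.0877). miR-204 and miR-211, known from the eye and of near-identical sequence, had nearly the same counts, with a log2 fold change of -2.04 for miR-204 (edgeR adjusted p = 0.0671). For miR-30a-5p the neural crest libraries read 209, 123.2 and 1191 CPM, and for miR-367, of the miR-302 cluster, 61.6, 58.7 and 374 CPM, so neural crest replicate 3 set both means.

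Counts or CPM of other muscle and vessel miRNAs follow. The muscle miRNA miR-133a-3p had 2, 4 and 18 counts in neural crest replicates 1, 2 and 3 and 0, 5 and 5 in neural plate, in libraries of unequal depth. miR-206, of skeletal muscle, read 912, 995 and 591 CPM in neural crest and 1887, 779 and 1254 in neural plate (edgeR adjusted p = 0.425). The endothelial miR-126-3p read 240.3, 202 and 905 CPM in neural crest and 547, 428 and 248 in neural plate (edgeR adjusted p = 0.898).

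The first pattern is the 15 called miRNAs with the miR-200 family among the tests of families, in libraries of unequal depth and spread. All 15 calls were kept without neural plate replicate 1 and neural crest replicate 3, so the other libraries differed for these miRNAs too. This cannot decide how far the libraries at the ends of the first component made the calls. What is left is the most alike pair of each group (r = 0.984 in neural crest and 0.986 in neural plate), with less spread. The sizes did change: the log2 fold change of miR-425-5p went from -3.17 to -1.26 and of miR-12277-5p from -4.05 to -1.89. Without neural crest replicate 3 alone edgeR made 0 calls (39 at an unadjusted p under 0.05). A library property that also varies within groups stays open: differences within the groups correlated over miRNAs with a mean r of 0.0361 (SD 0.0835, from -0.126 to 0.137 in 9 combinations). That mean lies below the 0.1 first set for excluding such a property. A demand that the mean plus the SD stay below 0.1 was added after a first run, and it was not met. The 9 combinations reuse the same 6 libraries, so the SD does not measure the uncertainty of the mean, and these values cannot decide. Only 1 of 10 splits of the 6 libraries, the real one, gave as many calls (15, highest other 0) or as many families (1, highest other 0), and 10 splits are too few for a share under 0.05. A difference between neural crest and neural plate, which the design names, stays open as well.

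The second pattern is that 14 of 29 hairpins with both arms tested had arms with opposite signs. That is near the even split that unrelated signs would give. Most of these arms were not called, and signs depend on scaling, with 36 changes over all tested miRNAs under library totals alone. A different abundance of the hairpins alone would leave arm ratios equal, and 1 hairpin differed in limma, miR-18b, whose log2 ratio of arms was higher in neural crest by 4.30 with a standard error of 1.12 (adjusted p = 0.0190; 6 at an unadjusted p under 0.05). Since 1 hairpin is neither 0 nor several, this stays open, and the miR-18b-5p arm had 0, 12 and 39 counts in neural plate and 12, 3 and 96 in neural crest. A library property that also varies within groups cannot be told apart either, with a mean r of 0.180 (SD 0.161) over arm ratios.

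The third pattern is that the authors' deposited table holds 12 genes higher in neural plate and 37 higher in neural crest by over 4 on the log2 scale, among them GCLM, NEXN and CDH1 and, towards neural crest, the crystallin gene CRYBA4 and ARIH1. Reads shared with an overlapping gene are a candidate explanation on the neural plate side, where 6 of 11 genes overlap another (54.5%, against 27.3% in random genes of like expression). That share lay at percentile 97.8 with ties counted at their middle, just past the level set beforehand, but 3.61% of draws were as large, so it stays open, and on the neural crest side the percentile was 73.5. The sorted cell types may account for part: 2 of the 37 neural crest genes (TFAP2B and PAX7) were among the crest and border lists, where 0.114 were expected (Fisher's exact p = 0.00572), which leaves most of the 37 unexplained. A batch that goes with the cell type cannot be told apart, since the series' labels used here hold 0 neural crest poly(A) libraries, and the 2 deposited count columns with names that point to neural crest match no labelled sample and were not used.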
